A study of Mus musculus with 2 samples.

How the data were processed

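Small RNAs below 30 nt were sequenced from the left cerebral cortex of female B6CASTF1/J mice, an F1 cross of a laboratory strain and a wild-derived strain, aged 25 days. The labels give 1 group with 2 biological replicates. The labels number the animals separately, while both libraries carry the same donor record, so their status as separate animals rests on the labels alone. Total RNA went through a multiplexed microRNA library protocol.

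The deposited tables hold read counts per microRNA gene, without normalization, on mouse build mm10 with GENCODE annotation M21. Each table was made from 1 FASTQ file. The aligner and the counting program are not given in the sources used here. The tables have no header. Their layout is that of strand-aware gene counts, with a column for reads on either strand, a column for the gene's own strand and a column for the opposite strand. These roles were read from the values. The own-strand column held 93.8% and 93.7% of the counts of both stranded columns in replicates 1 and 2, and it was used for all main values. A count joins both arms of a hairpin, so levels refer to microRNA genes and not to mature arms.

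The tables list 2202 microRNA genes, and all of their identifiers matched the M21 annotation on GRCm38, from which names, positions and overlapping genes were taken. They also give totals for reads that were unmapped, placed at several loci, outside any microRNA gene or ambiguous. These 4 classes were left out of library sizes. Own-strand microRNA gene counts summed to 3017058 in replicate 1 and 3209361 in replicate 2. A count of 0 allows a level of up to 0.994 CPM (the usual library-scaled count unit) in replicate 1 and 0.935 CPM in replicate 2, taken as 3 counts. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Per the file layout, reads placed at several loci form a class apart from the gene counts, so microRNA genes with identical mature sequences can be undercounted. Short-read alleles of the wild-derived strain were not examined.

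CPM values and shares of counts used the sum of own-strand microRNA gene counts, and are given as mean ± SD over the 2 replicates. A gene was called detected with at least 10 counts in both libraries. With a single group, no condition was compared. The libraries were compared with each other by a two-sided exact binomial test per gene, given TMM-scaled library sizes, over genes with at least 10 counts in total. Benjamini-Hochberg adjusted p under 0.05 counted as a call. The biological coefficient of variation (BCV) was the square root of the common dispersion of edgeR with an intercept alone. Log2 ratios are replicate 2 over replicate 1 after TMM scaling, with 95% counting intervals.

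20 lists of microRNA genes were fixed before the data were examined. They cover neurons, the miR-9 genes, astrocytes, oligodendrocytes, microglia and immune cells, endothelial and mural cells, mesenchymal cells, red blood cells, liver, striated muscle, epithelium, pancreas and pituitary, pluripotent cells, Hox clusters, ciliated cells and choroid plexus, the miR-183 cluster, let-7, the Dlk1-Dio3 cluster, miR-17~92 and its paralogs, and an X-linked testis cluster. The median log2(CPM + 1) of each list was placed among 10000 random lists of the same size drawn from all counted microRNA genes. List medians of the log2 ratio between replicates, with 1 CPM added to each level, used random lists matched on expression deciles, genes with a mean of at least 10 CPM and lists with at least 3 such genes. These percentiles are descriptions, because 2 animals cannot give an exact two-sided p below 0.5.

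Genes named by rule were the 25 with the highest mean CPM, up to 3 highest members of each list, and the 5 largest ratios in each direction between replicates among called genes with a mean of at least 50 CPM. Hairpins were compared with each other for shared stretches of at least 20 nt, on the annotated transcripts. The rest of the genome was not searched for copies.

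Alternatives, fixed before the data were examined except for leaving out each replicate from the read classes and Gm genes from the shared stretches, were the either-strand column, DESeq2 size factors, library totals, other count minimums, thinning to equal depth, other pseudocounts, other random lists, all reads as the denominator, shared stretches of 18 and 22 nt, and leaving out each replicate. On simulated counts, 200 genes were changed before the filter on counts, and 499 genes entered the binomial comparison. The test called 52% of 50 genes changed 1.25-fold, 57.4% of 47 changed 2-fold and 93.9% of 49 changed 4-fold. Among genes with at least 1000 counts it called 100% at each fold. It called 0.660% of 303 unchanged genes. The simulated counts held counting noise alone, so these rates leave out other differences between libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The seed was 1.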

Results

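Small RNA profiles were collected from the left cerebral cortex of female B6CASTF1/J mice aged 25 days, in 2 libraries labelled as separate animals. The libraries held 8491339 reads in replicate 1 and 9289252 reads in replicate 2. Of these, 35.5% (exact 95% interval 35.50 to 35.56) and 34.5% (34.52 to 34.58) were counted on the own strand of a microRNA gene. Reads placed at several loci made up 40.3% and 39.0%, unmapped reads 18.5% and 20.8%, and reads outside microRNA genes 5.59% and 5.69%. The labels describe an evaluation of RNA data from this tissue and set no condition against another. The measurements therefore describe which microRNA genes gave counts in the cortex, outside reads placed at several loci, and how closely the replicates matched.

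Among counted reads, which leave out those placed at several loci, the cortex profile was led by Mir139, let-7 genes and imprinted Dlk1-Dio3 microRNAs. Genes with identical mature sequences can therefore rank too low here. Mir139, a brain-enriched microRNA within an intron of the phosphodiesterase gene Pde2a, supplied 14.9% ± 0.984 of microRNA gene counts (SD, n = 2). It was followed by Mirlet7b at 7.36% ± 0.0396, Mirlet7g at 6.56% ± 0.597, Mirlet7i at 5.05% ± 0.599 and the Dlk1-Dio3 gene Mir127 at 4.57% ± 0.181. Mir744, within an intron of the kinase gene Map2k4, reached 4.37% ± 0.373, and the activity-regulated neuronal microRNA Mir132 reached 3.42% ± 0.138. The 10 highest genes, which included 5 let-7 genes, held 54.0% ± 1.66 of counts, and the 25 highest held 73.2% ± 0.584.

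On mm10, Mir139 (ENSMUSG00000065446.1) lies on the plus strand of chromosome 7 at 101475376 to 101475443. Mirlet7b lies on the plus strand of chromosome 15 at 85707319 to 85707403, in an exon of the noncoding gene Lncppara. Mirlet7g lies in an intron of Wdr82 on the plus strand of chromosome 9 at 106178840 to 106178927. Mirlet7i lies on the minus strand of chromosome 10 at 122985640 to 122985724, in an exon of the transcribed pseudogene D630033A02Rik. Mir744 occupies 65734733 to 65734832 on the minus strand of chromosome 11, and Mir132 occupies 75173682 to 75173747 on the plus strand of that chromosome, in an intron of the noncoding gene 1700016P03Rik. Of the 25 highest genes, 13 lay on the same strand within introns only of another annotated gene, 8 overlapped an exon on their strand, 2 overlapped genes on the opposite strand alone and 2 overlapped no other gene.

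Mirlet7e (2.81% ± 0.214), Mirlet7d (2.59% ± 0.834) and the Meg3 exonic gene Mir770 (2.36% ± 0.198) completed the 10 highest. Mir23b followed at 2.22% ± 0.269, Mir433 at 2.14% ± 0.0801 and Mir487b at 1.68% ± 0.488. Mir125a (1.32% ± 0.612), Mir128-1 (1.32% ± 0.188), Mir652 (1.247% ± 0.0320), Mir330 (1.21% ± 0.287), Mir382 (1.13% ± 0.0904) and Mir99a (1.08% ± 0.243) each held above 1%. Mir149, in an intron of the glypican gene Gpc1, averaged 1.24% ± 1.01, and its replicates stood apart at 0.534% without replicate 2 and 1.96% without replicate 1. Mir324, Mir541, Mir151, Mir99b and Mir23a ranged from 0.883% to 0.985%. With all reads as the denominator, the 25 highest genes held 25.7%.

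**Figure D1:**
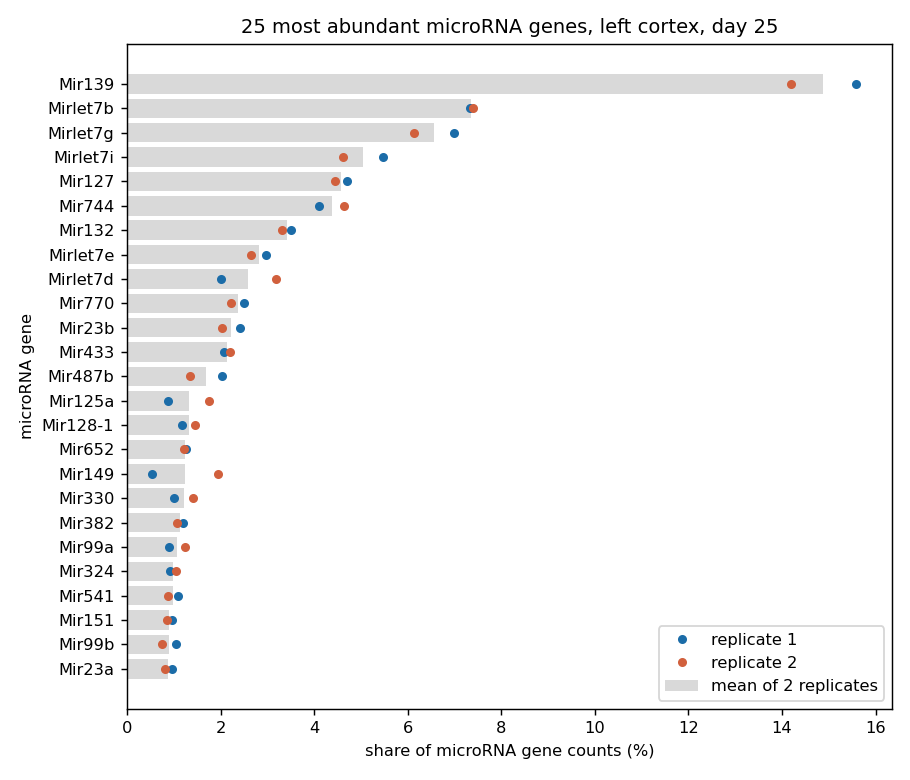
Share of microRNA gene counts, in percent, of the 25 genes with the highest mean level in the left cortex, with points for the replicates and bars for their mean (n = 2). Mir139 stands at 14.9% and Mirlet7b at 7.36%, and the replicates of Mir149 lie far apart at 0.534% and 1.96%.

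Detection was concentrated in a minority of the annotation. Of the 2202 counted microRNA genes, 395 were detected with at least 10 counts in both libraries, 742 had at least 1 count in either library and 1460 had 0 in both. On average, 200 genes reached 100 CPM and 99 genes reached 1000 CPM. Of 1021 genes with provisional names beginning with Gm, 7 were detected. The number of detected genes followed the minimum, with 613 at 1 count and 236 at 100 counts.

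Neuronal, let-7 and Dlk1-Dio3 microRNA genes together held 64.4% ± 2.10 of counts. The let-7 list held 25.2% ± 0.577, with all 12 genes detected and 8 at or above 1000 CPM. The neuron list held 22.1% ± 0.813, with 21 of 24 genes detected and 11 at or above 1000 CPM. Most of that share came from Mir139, which alone held 14.9% of microRNA gene counts. Beside Mir139, the highest members of the list were Mir132 at 34178 ± 1376 CPM and Mir128-1 at 13186 ± 1882 CPM. By contrast, the 3 genes of the neuronal microRNA miR-124 were near the floor, with 3 and 9 counts for Mir124a-1, 5 and 4 for Mir124a-3 and 0 and 3 for Mir124a-2 in replicates 1 and 2. The miR-9 genes, known from neural progenitors and neurons, held 0.00831% ± 0.00250, with Mir9-3 at 71.1 ± 20.8 CPM, Mir9-1 at 10.1 ± 4.53 CPM and Mir9-2 at 1.92 ± 0.370 CPM. All 3 Mir124a and all 3 Mir9 genes share a stretch of at least 20 nt with another microRNA gene, and reads placed at several loci were outside the gene counts.

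Glial and vascular lists, with 4 to 7 genes each, held smaller summed shares than the neuron list, while the median gene of the astrocyte (2888 CPM), oligodendrocyte (915 CPM) and endothelial and mural (514 CPM) lists stood above that of the neuron list (324 CPM) and that of the microglia and immune list (63.0 CPM) below it. The astrocyte list held 3.69% ± 0.396, led by Mir23b at 22192 ± 2686 CPM, Mir23a at 8833 ± 1029 CPM and Mir29a at 5296 ± 287 CPM, and all 6 of its genes were detected. The oligodendrocyte list held 0.464% ± 0.139, with Mir219a-2 at 2814 ± 626 CPM, Mir338 at 1827 ± 760 CPM and Mir219a-1 at 3.15 ± 3.04 CPM. The endothelial and mural list held 1.23% ± 0.0391, with the endothelial gene Mir126a, in an exon of Egfl7, at 7275 ± 2207 CPM, and the smooth muscle genes Mir143 and Mir145a at 4499 ± 1423 and 514 ± 393 CPM. The microglia and immune list held 0.263% ± 0.0313, with the lymphocyte microRNA Mir150 at 1765 ± 286 CPM, Mir146 at 715 ± 2.59 CPM and Mir142 at 65.2 ± 13.3 CPM. The miR-17~92 list, known from proliferating cells, held 0.372% ± 0.0362, led by Mir93 at 1770 ± 113 CPM, Mir17 at 853 ± 6.83 CPM and Mir92-1 at 424 ± 219 CPM.

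Lists of tissues and cell types outside the cortex each held under 0.05% of counts. The ciliated and choroid list held 0.0415% ± 0.0105, with Mir34c at 354 ± 138 CPM, Mir449a at 53.6 ± 31.7 CPM and Mir34b at 6.39 ± 1.54 CPM. The pancreas and pituitary list held 0.0143% ± 0.00449, nearly all from Mir375 at 135 ± 47.3 CPM, with Mir217 at 5.83 ± 2.07 CPM and Mir216a at 1.29 ± 0.0562 CPM. The epithelial list held 0.0135% ± 0.00197, led by Mir203 at 84.6 ± 35.9 CPM, Mir429 at 23.6 ± 13.3 CPM and Mir200c at 13.7 ± 3.10 CPM. Red blood cell microRNAs held 0.00632% ± 0.00172, with Mir451a at 32.0 ± 13.4 CPM, Mir486 at 21.8 ± 3.14 CPM and Mir144 at 9.46 ± 0.722 CPM. The hepatocyte microRNA Mir122, the sole liver gene, was at 48.9 ± 3.09 CPM. The muscle list held 0.00484% ± 0.000370, with Mir206 at 30.7 ± 5.02 CPM, Mir499 at 10.3 ± 8.40 CPM and Mir208b at 4.21 ± 1.55 CPM. Of the 10 muscle genes, 6 share a stretch of at least 20 nt with another hairpin. Among them Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir133b had 0 counts in both libraries. Reads of such genes can be placed at several loci, so their low counts need not be low levels.

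Mesenchymal genes held 0.00152% in replicate 1 and 0.00754% in replicate 2, with Mir214 at 32.7 ± 31.7 CPM, Mir1247 at 11.5 ± 10.6 CPM and Mir199b at 0.955 ± 0.413 CPM. Mir199a-1, Mir199a-2 and Mir199b share a stretch of at least 20 nt with another hairpin, so their counts can be too low. Hox cluster genes held 0.00520% and 0.00249%, with Mir10b at 27.1 ± 18.4 CPM, Mir10a at 7.08 ± 0.764 CPM and Mir196b at 3.87 ± 0.623 CPM. The miR-183 cluster of sensory organs held 0.000829% and 0.00206%, with Mir183 at 7.31 ± 3.77 CPM, Mir182 at 7.12 ± 4.91 CPM and Mir96 at 0 counts in both libraries. None of the 13 embryonic stem cell genes was detected, and Mir294, Mir302d and Mir302a had between 1 and 6 counts per library. Of 22 X-linked testis genes, Mir547 alone was detected at 7.57 ± 1.01 CPM, with Mir201 at 1.45 ± 0.291 CPM and Mir470 at 4 and 0 counts.

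Against random lists of the same size from all counted genes, 11 of the 20 lists lay at or above the 95th percentile. The neuron, let-7 and Dlk1-Dio3 lists were at 100, astrocyte at 99.98, miR-17~92 at 99.97, endothelial and mural at 99.91, microglia and immune at 99.82, oligodendrocyte at 99.25, epithelial at 98.7, ciliated and choroid at 96.6 and red blood cell at 96.0. The miR-9, miR-183, muscle, Hox, pancreas and pituitary, mesenchymal and liver lists lay between 89.5 and 93.9. The pluripotent list at 44.8 and the testis list at 46.0 were the 2 below the 50th percentile. Since 1460 counted genes had no reads, a list with few counts can rank high. In a further comparison each list was cut to its detected members and set against random lists from the 395 detected genes. There 5 lists stayed at or above the 95th percentile, namely neuron (99.55), astrocyte (96.9), endothelial and mural (97.1), let-7 (99.92) and Dlk1-Dio3 (99.98). The neuron list lost its near-floor Mir124a genes there. In the either-strand column, where reads over genes on both strands are ambiguous, the oligodendrocyte list stood at 61.2, the red blood cell list at 30.1, the muscle list at 39.5 and the endothelial and mural list at 90.4.

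**Figure D2:**
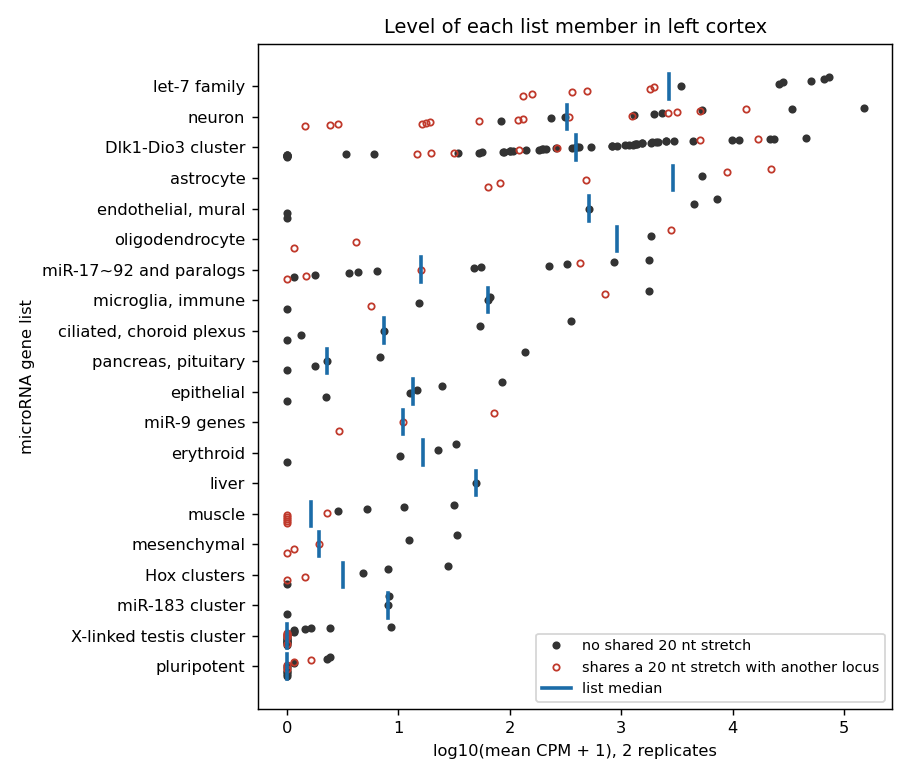
Mean level over the 2 replicates, as log10(CPM + 1), of each member of the 20 lists, with open circles for genes that share a stretch of 20 nt with another microRNA hairpin and vertical lines at the list medians. The let-7 median lies at 2699 CPM and the neuron median at 324 CPM, while the pluripotent and testis medians lie at 0.

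MicroRNA genes of the imprinted Dlk1-Dio3 locus, which are expressed from the maternal chromosome, gave counts from Meg3 to Mirg. Their list, which also holds Mir496b on chromosome 19 with 0 counts, held 17.2% ± 0.712 of counts, with 50 of 59 genes detected and 23 at or above 1000 CPM. Mir127 reached 45713 ± 1807 CPM, Mir770 23637 ± 1975 CPM and Mir433 21354 ± 801 CPM. Mir127 (chromosome 12, 109592846 to 109592915) and Mir433 (109591715 to 109591838) lie on the plus strand, opposite to an exon of the paternally expressed gene Rtl1. Mir770 (109563692 to 109563785) lies in an exon of Meg3, and Mir382 (109733771 to 109733846) in an exon of Mirg. From the start of Meg3 at 109541001 to the end of Dio3 at 110281097, 67 microRNA genes were counted, which is 3.04% of the genes in the tables and 17.2% ± 0.711 of counts.

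**Figure D3:**
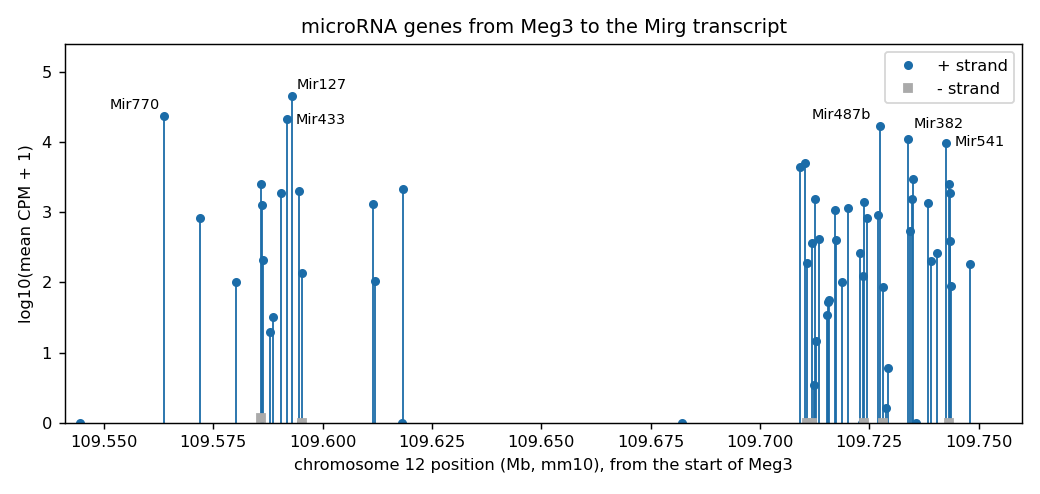
Mean level, as log10(CPM + 1), of the microRNA genes from the start of Meg3 to the end of Mirg on chromosome 12 (mm10), with plus-strand genes as circles and minus-strand genes as squares. Mir127, Mir770 and Mir433 are the highest, and Mir1247 beside Dio3 lies outside the plotted stretch.

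The replicates ranked microRNA genes alike, yet single genes differed by more than counting noise. Mir674 was 5.51-fold higher in replicate 1 than in replicate 2, with 29502 and 6675 counts (log2 ratio -2.46, 95% interval -2.50 to -2.42). Mir22, in an exon of its host gene Mir22hg on chromosome 11, was 3.42-fold higher in replicate 2, with 7263 and 31002 counts (log2 ratio 1.78, interval 1.74 to 1.81). The other large ratios toward replicate 1 were 4.04-fold for Mir380, 3.91-fold for Mir145a, 3.51-fold for Mir140, in an exon of Wwp2, and 2.57-fold for Mir376a. Toward replicate 2 they were 4.25-fold for Mir377, 3.94-fold for mmu-mir-3535, which overlaps the snoRNA gene Gm24148 and an exon of Ncl, 3.75-fold for Mir497 and 3.54-fold for Mir339. Mir380, Mir376a and Mir377 belong to the Dlk1-Dio3 cluster and did not differ in a single direction. Mir380, Mir376a and Mir497, as well as Mirlet7e, have 0 counts in the either-strand column.

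Across 496 genes with at least 10 counts in total, Spearman's rho was 0.961 and Pearson's r 0.979 for log2 CPM. These are correlations across genes, which are not independent replicates. The chi-square statistic over the same genes was 157523 on 495 degrees of freedom, or 318 per degree, which can include differences between animals and between library preparations. The BCV was 36.7%. Of 231 genes with a mean of at least 50 CPM, 32 (13.9%) were over 2-fold apart, and the median absolute log2 ratio was 0.42.

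The exact binomial test called 280 of the 496 genes, 152 higher in replicate 1 and 128 higher in replicate 2. Of these, 82 were over 2-fold apart. The test compares libraries and not conditions. TMM scaling moved the median log2 ratio by -0.23 relative to library totals, and directions are given relative to it. With library totals, 282 genes were called and the balance turned, with 102 higher in replicate 1 and 180 higher in replicate 2.

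Among 8 lists with at least 3 genes at 10 CPM or more, the endothelial and mural list had the median furthest from 0. Their median log2 ratio was -0.88, at percentile 1.29 of matched random lists, and 1 of 3 genes was higher in replicate 2. The endothelial gene Mir126a was higher in replicate 2 (log2 ratio 0.40), and the smooth muscle genes Mir143 and Mir145a were higher in replicate 1. The list median is the value of Mir143. Mir143 and Mir145a are neighbours on the minus strand of chromosome 18, at 61649196 and 61647825. Random lists drew genes singly, so the percentile counts these neighbours as separate members. The endothelial and mural list was the sole list outside the middle 95% of random lists, where chance gives 0.4 of 8. Microglia and immune genes had a median of -0.56 (percentile 6.88), let-7 genes -0.34 (14.5) and astrocyte genes -0.30 (29.2). The Dlk1-Dio3 genes were at -0.12 (38.5), neuron genes at -0.051 (69.7), epithelial genes at 0.0035 (44.0) and miR-17~92 genes at 0.083 (47.8). With library totals, the neuron and Dlk1-Dio3 medians turned to 0.17 and 0.11. Without the filter on low counts the miR-17~92 median turned to -0.16 and the epithelial median moved to 0.67, and with 5 CPM added in place of 1 the epithelial median turned to -0.0083.

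**Figure D4:**
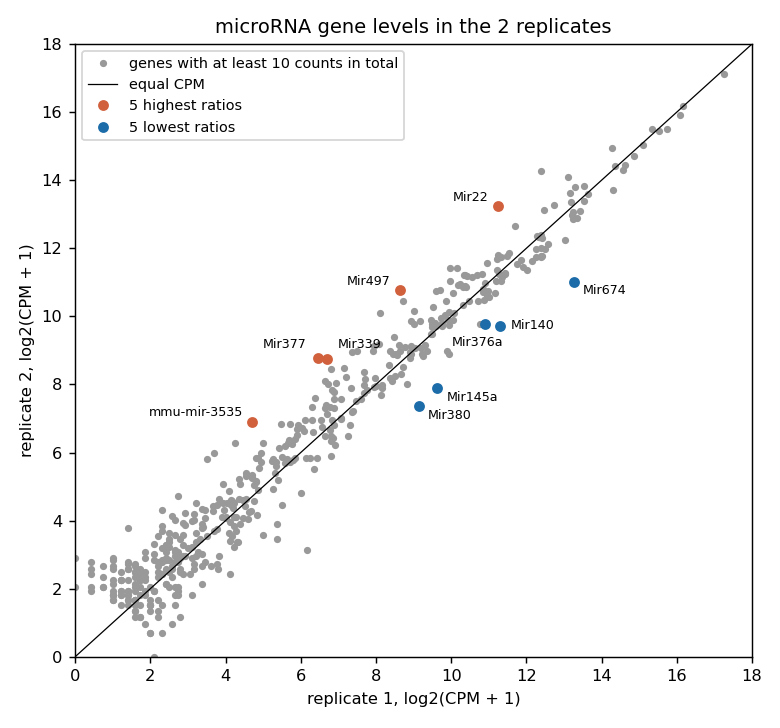
Level of each microRNA gene with at least 10 counts in total as log2(CPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), with the line of equal CPM. Mir22 and Mir377 stand above the line and Mir674 and Mir380 below it, among the 10 coloured genes with the largest ratios in each direction.

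Of the 2202 genes, 1087 share a stretch of at least 20 nt with another microRNA hairpin, and they held 11.0% ± 0.649 of counts. Of them 83 (7.64%) were detected, against 312 of 1115 genes (28.0%) that share none, but 824 of the 1087 have provisional Gm names. Without Gm genes, a split chosen after the values were seen, 81 of 263 sharing genes (30.8%) and 307 of 918 others (33.4%) were detected. Among the 25 highest genes, Mir23b, Mir487b, Mir128-1 and Mir23a share such a stretch. Within let-7, Mirlet7b, Mirlet7g, Mirlet7i, Mirlet7e and Mirlet7d share none, while Mirlet7f-2 at 1956 CPM, Mirlet7c-2 at 1814 CPM, Mirlet7c-1 at 488 CPM, Mirlet7a-1 at 359 CPM, Mirlet7f-1 at 156 CPM and Mirlet7a-2 at 131 CPM do. The share of counts depended on the length of the stretch, at 30.7% for 18 nt and 4.90% for 22 nt.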

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

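The tests of neural microRNA genes by shared stretches, their repeats on other genes, and the tests of neighbouring genes within the Dlk1-Dio3 list and among called genes were chosen only after the result was seen.

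Reads placed at several loci drew attention because they lie outside the gene counts and made up 40.34% of reads in replicate 1 and 38.99% in replicate 2. Such a loss may bear on the low counts of the Mir124a and Mir9 genes, which have several copies. Among the 39 genes of the neuron, miR-9 and let-7 lists, the 24 that share a stretch of at least 20 nt had a median of 130.7 CPM and the 15 that share none 5340 CPM, a difference of -5.34 on the log2 scale, but this set holds the genes in which the pattern was noticed. In the 21 neuron genes without Mir124a the difference was -3.21 (two-sided permutation test, p = 0.18). In 117 genes of the cortex cell type, Dlk1-Dio3 and miR-17~92 lists without Mir124a it was -1.63 (permutation p = 0.20). The 117 include those 21, and neither set holds a Mir124a or Mir9 gene. The explanation therefore stays open for the other sharing genes, and these repeats do not bear on Mir124a and Mir9. Reads placed at several loci are not given per gene, so the number lost at the Mir124a and Mir9 genes cannot be counted. Low counts at every copy follow from such a loss and also from low transcription of every copy. The Mir124a genes stood at 1.90, 1.45 and 0.467 CPM and the Mir9 genes at 71.1, 10.1 and 1.92 CPM. These values do not tell the explanations apart. Differences in transcription between copies stay open as well, for these and the other sharing genes. No biological explanation was tested, as the design gives a single group.

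The replicates differed by more than counting noise at 280 of 496 tested genes. Joint change of clustered genes was examined by the correlation of log2 ratios over pairs of same-strand genes within 10 kb. It bears only on genes with such a neighbour, and the pairs of called genes hold 101 genes. Over 364 pairs it was -0.00389 (bootstrap 95% interval -0.051 to 0.257), which argues against joint change of the paired genes as a set. However, 295 of these pairs lie within the Dlk1-Dio3 list. There the correlation was -0.0377 (-0.154 to 0.127, genes resampled), which argues against joint change of that locus between these 2 libraries. That interval covers the spread over genes of 1 locus and not over clusters. Outside that list 69 pairs gave 0.176 (-0.095 to 0.366), and the 35 pairs of called genes, at 0.217 (-0.196 to 0.516), leave it open. A cubic trend on the GC content of whole hairpins was removed. The SD of log2 ratios among the better counted genes was 0.745 before and 0.730 after, which argues against hairpin GC as the whole cause. Of the 280 calls 251 stayed calls, but at high counts the test calls even small differences, so this count alone decides little. Log2 ratios rose weakly with GC across 231 genes (Spearman's rho 0.174, permutation p = 0.0080, 0.016 adjusted over 2 relations). The GC content of the sequenced reads was not examined. Reads shared between annotated microRNA copies are argued against as the whole cause, because 54.3% of 405 genes without a shared stretch were called (exact 95% interval 49.3 to 59.2), against 65.9% of 91 genes with a shared stretch. Differences between the animals, their dissection and their library preparation stay open, untested with 1 library per labelled animal.

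Counts in the unused opposite-strand column, at microRNA genes without an overlapping partner gene, summed to 94 in replicate 1 and 95 in replicate 2, or 0.00312% and 0.00296% of own-strand counts.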

How the results depend on the processing

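Of the alternatives given here, the read classes without each replicate and the shared stretches without Gm genes were chosen only after the data were seen. Multimapping reads then ranged from 39.0% to 40.3%.

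Detected genes ranged from 370 to 510 with the either-strand column, a minimum of 3 counts, thinning to equal depth or either replicate left out, against 395. A minimum of 1 count gave 613 and a minimum of 100 counts gave 236, by construction. The share of the 25 highest genes was 73.2%. For these same genes it was 73.6% in replicate 1 and 72.8% in replicate 2. With the 25 highest chosen anew, the share was 73.2% to 74.2% when each replicate was left out. It was 76.3% with the either-strand column, where overlapping genes make reads ambiguous and Mirlet7e falls to 0, and 25.7% with all reads as the denominator. The number of lists at or above the 95th percentile was 11, and 8 to 11 under the either-strand column, a pseudocount of 0.1 CPM or either replicate left out. Random lists from detected genes gave 5, with genes that were not detected left out of both the background and the lists. The pluripotent list has no detected member and no value there. The either-strand column put the oligodendrocyte list at percentile 61.2, the red blood cell list at 30.1 and the muscle list at 39.5.

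Spearman's rho between replicates was 0.957 with the either-strand column and 0.934 with no filter, against 0.961. The BCV was 0.366 to 0.387 when the column, the scaling or the filter was changed alone. Calls between replicates numbered 259 to 282. The share of calls higher in replicate 2 was 45.7%, and 46.4% to 49.0% in the other settings except library totals, where it was 63.8%, through the shift of the median by 0.23. All 10 named ratios kept their direction with DESeq2 size factors, library totals and no filter. These settings shift log2 ratios nearly alike, by 0.0090, 0.23 and 0.024, while the smallest named ratio was -1.36. No direction could therefore turn. The either-strand column gave the same direction for 7 of the 10 ratios and no value for Mir380, Mir376a and Mir497, whose reads become ambiguous there. The count of lists outside the middle 95% was 1 in all settings except the either-strand column, where it was 0 because the endothelial and mural list had fewer than 3 genes left. Shared stretches of 18 nt covered 30.7% of counts and those of 22 nt 4.90%, against 11.0% for 20 nt with or without Gm genes. Depth limits genes below about 1 CPM, where 3 counts cannot be told from 0.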

Other observations

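The groupings below and the values by chromosome and family were chosen only after the data were seen.

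Several families outside the fixed lists each held above 0.5% of counts. The Mir99 and Mir100 genes held 2.28% ± 0.0967 of counts (SD, n = 2), Mir30 genes 1.46% ± 0.304, Mir125 genes 1.45% ± 0.624, Mir181 genes 0.771% ± 0.0153 and the vascular and neuronal pair Mir221 and Mir222 0.706% ± 0.112. Within the Mir30 family 6 of 7 genes were detected, and within the Mir181 family all 6. A stretch of at least 20 nt is shared with another hairpin by 4 of 6 Mir181, 2 of 5 Mir125 and 2 of 7 Mir30 genes. The Mir99, Mir100, Mir221 and Mir222 genes share none, so the order of these families can be distorted by reads placed at several loci. The Mir344 genes were low at 0.00537% ± 0.000992, with 3 of 13 detected, and 12 of the 13 share a stretch of at least 20 nt with another hairpin.

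MicroRNA genes of the X chromosome held 3.79% ± 0.0302 of counts, with 35 of 142 genes detected. Mir652, in an intron of Tmem164, was the highest of them at 1.247% ± 0.0320. The repeat-like families Mir297, Mir466, Mir467 and Mir669 held 0.185% ± 0.0160, with 8 of 81 genes detected, and 79 of the 81 share a stretch with another hairpin. Genes with provisional Gm names held 0.0519% ± 0.0115.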
